A study of Mus musculus with 6 samples.

How the data were processed

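Gene expression was measured by RNA sequencing in 6 libraries labelled as liver of male C57BL/6 mice aged 10 weeks, 3 as control and 3 as low-dose tunicamycin. Tunicamycin blocks N-linked glycosylation by inhibiting the enzyme DPAGT1, so that unfolded glycoproteins accumulate in the endoplasmic reticulum (ER). Per the labels, the treated mice received 0.2 mg/kg by daily intraperitoneal injection for 14 days. Whether the controls were injected with vehicle is not given in the sources used here. Nothing in the labels states that each library came from a separate mouse, so the spread between libraries need not be that between mice and may be partly technical.

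Per the labels, ribosomal RNA was depleted from total RNA before stranded, paired-end libraries were made and sequenced on an Illumina HiSeq. The submitters' processing notes name CASAVA 1.8, cutadapt 1.9.3 for trimming, HISAT2 2.0.4 for alignment to the mouse genome build mm10, and Cuffdiff with an Ensembl annotation for gene-level values. The Cufflinks version is not given in the sources used here. The authors deposited FPKM (fragments scaled to transcript length and to the fragments of the library) for 22564 protein-coding genes in each of the 6 libraries. 1 further line of the table was not analysed here. The authors also deposited an estimated count per gene and library. These count columns are not whole numbers, and their scaling is not given in the sources used here. In each library, 97.2% to 98.0% of the values above 0 were whole multiples of a single step (within 0.01 of a multiple), and the step lay between 0.9953 and 1.0953. Dividing by the step and rounding gave whole reads per gene, 541022 to 661145 reads per library. Those totals cover protein-coding genes only. At these depths a read number of 0 allows up to 0.000454% to 0.000555% of a library's reads (3 reads per library). That bound covers counting error only, since reads copied from the same molecule are not independent.

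Groups and replicate numbers were taken from the sample labels. The main test was limma 3.58.1 (R 4.3.3; empirical Bayes with a variance trend, group as the only term) on log2(FPKM + 1), over the 7696 genes with a mean FPKM of at least 1 across the 6 libraries, with Benjamini-Hochberg adjusted p under 0.05, 2-sided. With all 6 libraries the limma variance prior had infinite degrees of freedom. Each gene's limma SE and p therefore came from the variance trend over genes of like abundance, and its own spread between replicates had no weight. Log2 fold changes are tunicamycin minus control on the log2(FPKM + 1) scale, which understates changes of low genes. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and with fry beside it. Of 52 lists (pathways, liver zones, markers of other cell types, and RNA quality), 36 had at least 5 members among the genes tested. The test, the lists, the rule for named genes and most alternatives were set before the data were examined. That plan also said that edgeR would replace limma if the values were counts. The table holds FPKM, as the plan assumed, and its count columns are scaled estimates. limma on FPKM therefore stayed the main test, and edgeR 4.0.16 (quasi-likelihood, TMM scaling) and DESeq2 1.42.0 (poscounts size factors), both on the whole reads, were added as alternatives. That decision preceded the results of either test, and it is a choice on which the plan can be read both ways.

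The genes named are, first, 18 preset genes of ER stress, glucose, bile acid, lipid and albumin metabolism. To these were added, in each direction, up to 8 genes past the threshold with a mean FPKM of at least 5 in the higher group and no overlap between groups, ranked by log2 change. Where fewer than 8 passed, the remainder were the genes with the smallest unadjusted p, stated as having missed the threshold. In each list discussed, up to 4 members with the smallest p could be named. The called genes outside this rule, genes named for being listed at 0 and genes named for their abundance were chosen after their values were seen. Gene positions are those of GENCODE M21, on the same build, which held 21839 of the table's gene identifiers. An FPKM of exactly 0 can be a failed estimate, so genes with such values are described as listed at 0, with the value of each library. In each library, 96 to 147 genes had an FPKM above 0 without a read, and they are counted as above 0.

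Both test steps were tested on simulated data in which each library held as many molecules as its reads divided by its most frequent read number per gene. Of 6748 simulated genes tested, limma recovered 1 of 67 genes changed 4-fold, 1 of 67 changed 16-fold and 11 of 66 changed 64-fold, with 1 false call. edgeR recovered 1, 13 and 34 of them. Camera recovered 4 of 5 lists shifted 2-fold and 5 of 5 shifted 4-fold, and called a list in 2 of 20 draws with no shift. Alternatives covered the pseudocount, the filter on low values, the scaling between libraries, the variance trend, a replicate block, each replicate left out in turn, the threshold, the correlation used for lists, and the set test. Chosen after seeing the data were the 2 count tests, a restriction to genes above 0 in all 6 libraries, and reads divided by the most frequent read number of their library. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.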

Results

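Gene expression was compared between libraries labelled as liver of control mice (n = 3) and of mice given low-dose tunicamycin (n = 3), an inhibitor of N-linked glycosylation. The deposited table gave FPKM for 22564 protein-coding genes, and whole reads recovered from its count columns numbered 541022, 577234 and 661145 in control libraries 1, 2 and 3 and 611041, 553793 and 595501 in tunicamycin libraries 1, 2 and 3. Of these genes, 13826 were listed at 0 in all 6 libraries and 1124 were above 0 in all 6. Genes above 0 numbered 3046, 5035 and 5095 in the controls and 5482, 4244 and 4300 after tunicamycin, so that control 1 held the fewest. Housekeeping genes were unevenly listed. Gapdh, a glycolytic enzyme, was at 0 in control 1, tunicamycin 1 and tunicamycin 3, at 1.83 FPKM in control 2, at 633 in control 3 and at 151 in tunicamycin 2, whereas Actb, a cytoskeletal actin, lay between 1176 and 1935 FPKM in all 6. Across the 7696 genes tested, the correlation of log2(FPKM + 1) between libraries was 0.28 to 0.35 within a group and 0.27 to 0.38 between groups, over 15 library pairs (across genes, which are not independent replicates).

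Reads per detected gene were bunched. The most frequent read number per gene was 139, 46.1 and 53.4 in control 1, 2 and 3 and 40.4, 68.3 and 70.7 in tunicamycin 1, 2 and 3, and 1340 to 2102 genes of each library lay within 1.5-fold of it. Lars2, the mitochondrial leucyl-tRNA synthetase, took 14.5%, 16.6% and 16.03% of the reads in the controls and 23.3%, 16.7% and 18.5% after tunicamycin. Mitochondrially encoded genes took 4.15%, 8.69% and 8.12% of the reads in the controls and 6.33%, 6.58% and 4.84% after tunicamycin.

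**Figure D1:**
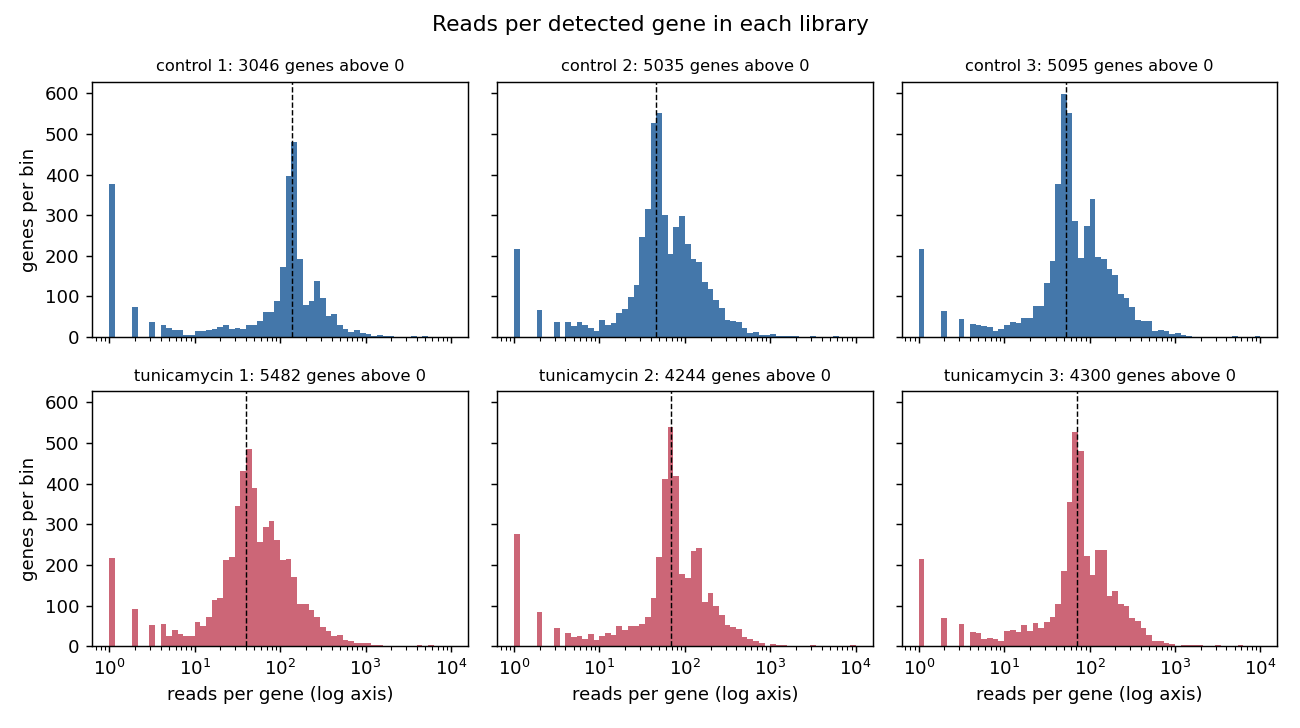
Histograms of whole reads per detected gene in each of the 6 libraries (x axis, reads per gene on a log axis; y axis, genes per bin), with a dashed line at the most frequent read number. Genes bunch at 139 reads in control 1 and at 40.4 to 70.7 reads in the other 5 libraries.

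The first question was which tissue and cell types the libraries represented, since the treatment acts on secretory cells of the liver. Many genes of liver function were listed at 0, in some lists more than in others. Of 34 genes for secreted plasma proteins, 29 were at 0 in all 6 libraries, among them Ttr, Serpina1a, Ahsg and Apoh. Albumin (Alb) lay at 248 ± 46.4 FPKM in controls and 119 ± 19.7 after tunicamycin (SD, n = 3 each), and Rbp4, the retinol carrier, at 259, 156 and 191 FPKM in controls and 49.5, 169 and 74.9 after tunicamycin. The other 3 plasma protein genes above 0 (Hpx, F11 and Pros1) were each at 0 in at least 4 libraries. At 0 throughout were also 20 of 22 periportal genes (Cps1, Ass1 and Arg1 of the urea cycle among them), 28 of 36 xenobiotic genes, 22 of 29 amino acid and urea genes, 21 of 28 bile acid genes, 13 of 18 complement genes and 18 of 29 acute phase genes. Over all genes of the table, 13826 of 22564 were at 0 throughout. The acute phase share (62.1%) was close to that of all genes, and it does not mark that list as missing. Fewer were at 0 throughout in cholesterol synthesis (4 of 24), fatty acid and triglyceride synthesis (5 of 23) and gluconeogenesis (7 of 23). The male-biased list, which holds the major urinary proteins, was at 0 for 24 of 27 genes, and the female-biased list for 22 of 26.

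Pericentral genes divided. Cyp2e1 and Cyp1a2, cytochromes P450 of pericentral hepatocytes, were at 0 in all 6 libraries, as were 11 of the 24 genes of that list, while glutamine synthetase (Glul) lay at 172, 113 and 128 FPKM in controls and 189, 145 and 211 after tunicamycin. The WNT target Axin2 lay at 64.4, 89.9 and 29.0 FPKM in controls and 70.4, 19.0 and 95.6 after tunicamycin. Of 16 hepatocyte transcription factors, 11 were above 0 in at least 1 library. Hnf4a, a master regulator of hepatocyte genes, was above 0 in all 6, at 262, 23.9 and 7.58 FPKM in controls and 6.99, 17.4 and 8.85 after tunicamycin. Its reads numbered 115, 185 and 62 in controls and 57, 132 and 70 after tunicamycin, so its FPKM in control 1 is uncertain. FPKM and reads also disagreed for Usp14 and Asns below.

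Markers of the other cells of a liver piece were also largely at 0 in all 6 libraries, namely 13 of 13 for neutrophils, 16 of 16 for T and NK cells, 10 of 10 for B and plasma cells, 11 of 13 for Kupffer cells, 18 of 20 for endothelium, 15 of 18 for stellate cells and fibroblasts, 9 of 11 for mesothelium, 8 of 10 for red blood cells, 7 of 8 for adipose tissue and 15 of 15 for exocrine pancreas. The monocyte list was at 0 for 9 of 14 genes, close to the share of all genes (13826 of 22564), and its abundant member Lgals3, a lectin that many cell types express, lay between 48.7 and 522 FPKM. Cholangiocyte markers were at 0 for 8 of 15, and the epithelial keratins Krt7 and Krt19 were above 0 in all 6 libraries, Krt7 at 118 ± 74.1 FPKM in controls and 26.6 ± 26.1 after tunicamycin and Krt19 at 41.1 ± 37.7 and 105 ± 59.4 (SD, n = 3 each). Neither keratin passed the test (limma adjusted p = 0.852 for both), and with 1 library left out the ratio of tunicamycin to control means was 0.10 to 0.32 for Krt7 and 1.74 to 5.01 for Krt19.

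Genes of the ribosome, the mitochondrial genome, the proteasome and the cell cycle were detected. None of 41 cytosolic ribosomal protein genes, 13 mitochondrially encoded genes and 30 cell cycle genes was at 0 in all 6 libraries, and 1 of 33 proteasome genes was. Mki67 and Top2a, markers of dividing cells, were above 0 in all 6 libraries, Mki67 between 25.5 and 37.8 FPKM and Top2a between 27.8 and 256. Lars2 and the mitochondrial genes aside, the highest means were those of Hist1h4d, a histone gene (1884 FPKM over the 6 libraries), Eef1a1 (1772), Actb (1570) and Rps26 (1525). Tmsb10 (983) and Fth1 (970) followed, and S100a11 (761) and Sprr1a (539) stood further down among other genes. Y-linked genes were nearly absent from libraries labelled male: Ddx3y, Eif2s3y, Kdm5d and Uty held 1 read in total (Uty, tunicamycin 2), against 2020 reads of their X-linked partners Ddx3x, Eif2s3x, Kdm5c and Kdm6a. These values apply to both groups, and each gene group below was measured in the same libraries.

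**Figure D2:**
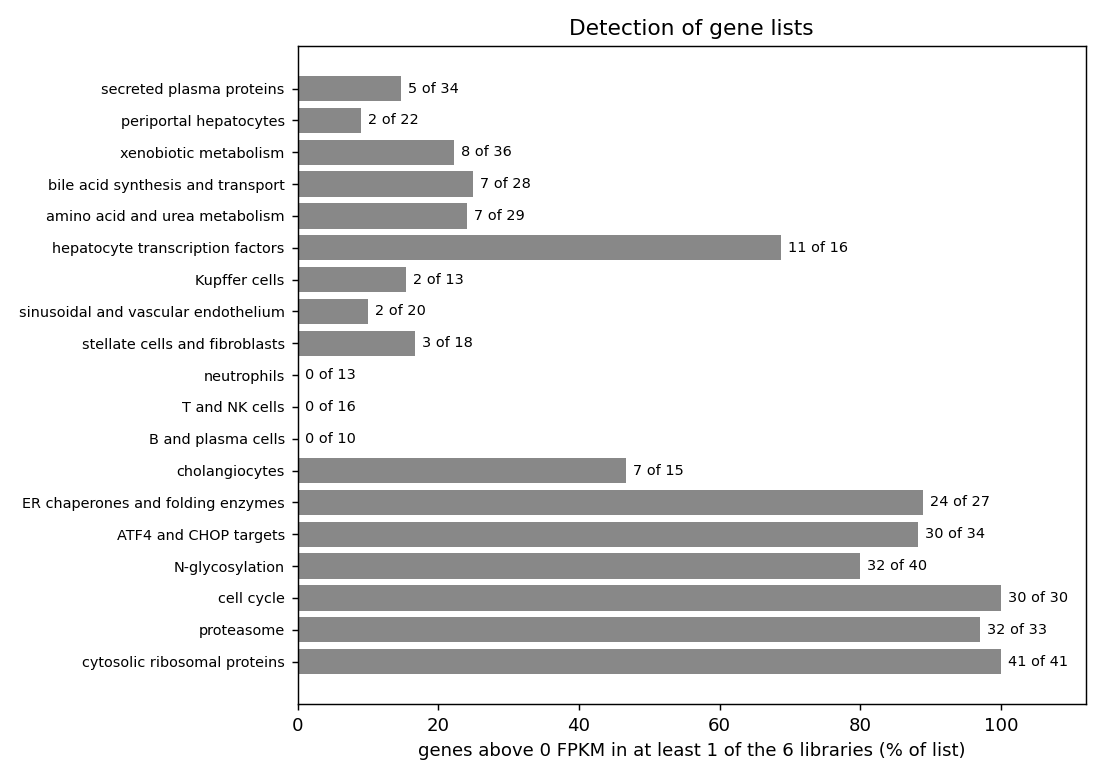
Bars give the percent of each gene list above 0 FPKM in at least 1 of the 6 libraries (x axis; counts at the bar ends). Lists of plasma proteins (5 of 34), periportal, xenobiotic, bile acid and amino acid genes and of blood and vessel cells lie low, hepatocyte transcription factors lie higher (11 of 16), and cell cycle genes (30 of 30) and ribosomal protein genes (41 of 41) were all detected.

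The design then asks which genes differ between tunicamycin and control. Usp14, a proteasome-associated deubiquitinase, rose from 5.15 ± 3.50 FPKM in controls to 538 ± 180 after tunicamycin (SD, n = 3 each), a 105-fold ratio of means and a log2 fold change of 6.64 (SE 1.27; limma adjusted p = 0.000712). Its reads numbered 270, 77 and 4 in controls and 1572, 2058 and 3006 after tunicamycin, higher in 3 of 3 libraries, a smaller ratio of 18.9 (6636 against 351 reads in total; 54.6 without control 1 and 12.8 without control 3), and edgeR and DESeq2 on reads gave log2 fold changes of 4.45 and 4.08. Reads and FPKM of Usp14 implied transcripts of 20772 and 6385 nt in controls 1 and 2, longer than those annotated, so the control FPKM and the larger ratio are uncertain. Rpl15, a ribosomal protein, rose from 2.93 ± 1.88 to 473 ± 150 FPKM (log2 fold change 7.01, SE 1.38, limma adjusted p = 0.00103), and Rps26, another ribosomal protein, fell from 2035 ± 579 to 1016 ± 530 FPKM (log2 fold change -1.14, SE 0.27, limma adjusted p = 0.0388). Both have near-identical pseudogene copies between which reads can be split, so their values are uncertain. Usp14 lies on chromosome 18 at 9993066 to 10045119, Rpl15 on chromosome 14 at 18267823 to 18271391 and Rps26 on chromosome 10 at 128624534 to 128626747 (mm10).

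The other called genes were Lars2 and mt-Cytb. Lars2 stood at 13497 ± 1410 FPKM in controls and 16431 ± 3019 after tunicamycin (log2 fold change 0.27, SE 0.06, limma adjusted p = 0.0187), with tunicamycin 2 (13807 FPKM) below control 2 (13950) and control 3 (14625). Its mouse locus (chromosome 9, 123366927 to 123462666) holds sequence similar to ribosomal RNA, so its reads are uncertain too. mt-Cytb, the mitochondrially encoded cytochrome b (mitochondrial genome, 14145 to 15288), was called higher (log2 fold change 2.98, SE 0.43, limma adjusted p = 2.94e-08), a call that rests on control 1, where it held 0 reads. It held 4601 and 6615 reads in the other controls and 4008, 3065 and 2240 after tunicamycin, and without control 1 its log2 fold change was -0.87. The limma SE of Lars2 and of mt-Cytb came from the variance trend and not from the spread of these genes between replicates.

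**Figure D3:**
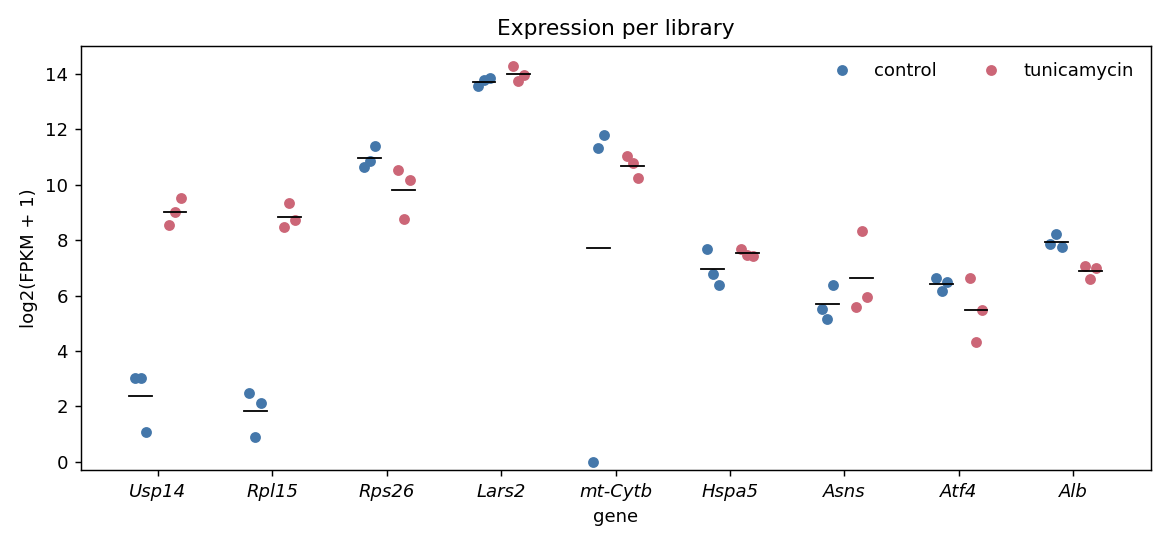
Expression of 9 genes on the log2(FPKM + 1) scale (y axis), each point 1 library (blue, control; red, tunicamycin; n = 3 each) and each line a group mean. The groups do not overlap for Usp14, Rpl15, Rps26 and Alb, with the widest gaps for Usp14 and Rpl15. The control mean of mt-Cytb is drawn down by 1 library, and Hspa5, Asns, Atf4 and Alb did not pass the test.

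In all, 5 of 7696 genes passed limma's threshold, 4 higher and 1 lower, and 238 had an unadjusted p under 0.05, against 384.8 if p-values were uniform. The 2 groups did not overlap for 442 genes (5.74%), and the 9 other splits of the libraries into 3 and 3 gave 432 to 559 such genes. The 10% that chance gives without ties does not apply, since 85.5% of the genes tested were at 0 in at least 1 library. edgeR on whole reads called 3 genes, Usp14, Rpl15 and Lars2, with 115 at an unadjusted p under 0.05. For Lars2 the edgeR adjusted p was 1.57e-248 at a read ratio of 1.23. Its groups overlapped in reads (92760 in tunicamycin 2, 95728 in control 2), so that p-value does not reflect their spread and the call is uncertain. DESeq2 called 44, 20 higher and 24 lower, with 446 at an unadjusted p under 0.05 and no adjusted p for 4202 genes, and of its calls Rpl15 alone was among the 5 (the DESeq2 adjusted p of Usp14 was 0.109). With median-of-ratios scaling the split was 4 higher and 0 lower, without Rps26. With quantile scaling it was also 4 higher and 0 lower, but Lars2 was lost as well and Rps29 was gained. No gene was called when any single library was left out, control 1 included, with the variance trend removed or with a replicate block.

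The next genes by unadjusted p whose groups did not overlap missed limma's threshold. DESeq2 called 2 of them, Timm8b (DESeq2 adjusted p = 0.0487, 0.0487 to 0.886 over the settings) and H2-Ke2 (DESeq2 adjusted p = 0.0220, 0.0220 to 0.886). Their reads above 0 were of the order of the most frequent read number of a library (Timm8b 59, 91 and 79 after tunicamycin, H2-Ke2 118, 30 and 152 in controls). Between libraries of a group, 22.6% to 51.0% of genes with at least 50 reads in 1 library held 0 in another. Such gaps thus also arose between replicates, and both calls are uncertain. On the higher side, Timm8b, a mitochondrial import chaperone, was at 0 in all 3 controls and at 82.5, 143 and 118 FPKM after tunicamycin (limma adjusted p = 0.237), and Gmppa, a regulator of GDP-mannose synthesis, was at 0 in all 3 controls and at 42.0, 26.7 and 127 FPKM (limma adjusted p = 0.795). Mrps18b, H3f3a, Atp5g1 and Hypk made up that side, each with 0 reads in at least 1 control. On the lower side, H2-Ke2 lay at 178, 48.0 and 239 FPKM in controls and at 0 in all 3 tunicamycin libraries (limma adjusted p = 0.190), and Stoml2 at 134, 57.4 and 37.3 FPKM and then at 0 in all 3 (limma adjusted p = 0.701). Mff, Rbm38, Tceb2, Cox7c and Myl6 completed that side, each at 0 in at least 1 tunicamycin library.

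Genes of the unfolded protein response, which ER stress induces, were measured in part. None of the preset genes passed except Usp14. Hspa5, the ER chaperone BiP, lay at 132 ± 63.98 FPKM in controls and 183 ± 16.2 after tunicamycin (log2 fold change 0.58, SE 0.84, limma adjusted p = 0.869). Atf4, the transcription factor of the integrated stress response, lay at 85.7 ± 14.5 and 53.7 ± 40.6 FPKM (log2 fold change -0.94, SE 1.20), and its target Asns, asparagine synthetase, at 54.2 ± 25.5 and 142 ± 152 FPKM (log2 fold change 0.93, SE 1.14; SD, n = 3 each). Both values depended on tunicamycin 2, since without it the log2 fold change was -0.37 for Atf4 and 0.08 for Asns. Reads of Asns totalled 320 in controls and 329 after tunicamycin (ratio 1.03), so its rise in FPKM was not seen in reads. Ddit3, which encodes CHOP, was at 0, 0 and 60.6 FPKM in controls and 55.0, 96.4 and 0 after tunicamycin. Trib3 was at 0, 89.3 and 0 FPKM and then at 0, 71.6 and 35.1, Herpud1 at 128, 0 and 2.12 and then at 1.09, 0 and 0.95, Sdf2l1 at 102, 0 and 0 and then at 19.6, 33.8 and 0, while Xbp1 held reads in control 3 (46.5 FPKM) and tunicamycin 2 (0.77 FPKM) and none in the other 4 libraries. Dnajb9, Fgf21 and Dpagt1, the target of tunicamycin, were at 0 in all 6 libraries.

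Of 24 measured ER chaperones and folding enzymes, 14 had a positive and 10 a negative log2 fold change, and none passed over all genes or adjusted over the list alone (median 0.31, camera adjusted p = 0.734). P4hb, a protein disulfide isomerase, lay at 137 ± 74.8 FPKM in controls and 344 ± 209 after tunicamycin, and Calr, calreticulin, at 353 ± 339 and 156 ± 113 (SD, n = 3 each). The gap for Calr rested on control 1 (737 FPKM), without which the ratio of means was 0.97 instead of 0.44. Among 28 ATF4 and CHOP targets, 16 were positive, 12 negative and none passed either adjustment (median 0.87, camera adjusted p = 0.823). Psat1 lay at 69.8 ± 47.6 and 171 ± 83.9 FPKM and Phgdh at 200 ± 51.1 and 88.8 ± 41.7 (SD, n = 3 each), both enzymes of serine synthesis. Without control 3 the ratio of means for Psat1 was 4.04 instead of 2.45. ER-associated degradation (13 of 20 positive, median 0.66, camera adjusted p = 0.734), sensors of the response (8 of 14 positive, median 0.28, camera adjusted p = 0.890) and N-glycosylation (12 of 26 positive, median -0.04, camera adjusted p = 0.836) held no gene that passed either adjustment. In ER protein translocation 12 of 23 genes were positive (median 0.14, camera adjusted p = 0.734), and in ER to Golgi transport 23 of 32 (median 0.83, camera adjusted p = 0.734), again with none past either adjustment by limma. DESeq2 called Srp9 of the translocation list, at 0 in all 3 controls and at 35.8, 59.8 and 29.3 FPKM after tunicamycin (limma adjusted p = 0.852). Its reads there were 66, 129 and 36, of the order of the most frequent read number of a library, so this call is uncertain too. Single libraries moved the medians of these lists. For the ER chaperones the median was 0 without tunicamycin 1, 0.02 without tunicamycin 3 and at most 0.46 with another library left out. Without control 1 it was -0.01 for the ATF4 and CHOP targets, -0.04 for ER-associated degradation, -0.37 for the sensors, -0.58 for N-glycosylation, -0.28 for ER protein translocation and -0.09 for ER to Golgi transport, and the highest values with 1 library left out were 0.89, 0.95, 0.94, 0.70, 0.97 and 1.28.

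Pck1, G6pc and Gcgr of gluconeogenesis and glucagon action, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, were at 0 in all 6 libraries. The list of gluconeogenesis and glucagon action, as written beforehand, included the deubiquitinase Usp14. Of the 14 measured members of that list Usp14 alone passed, over all genes and adjusted over the list alone (camera adjusted p = 0.734). Srebf1, a regulator of lipid synthesis, was at 192, 0 and 11.4 FPKM in controls and 3.82, 358 and 3.40 after tunicamycin. Fatty acid and triglyceride synthesis (11 of 16 positive), cholesterol synthesis (11 of 19 positive, with a median of 0.34, or -0.42 without tunicamycin 2, and a mean of -0.06), fatty acid oxidation (10 of 16 negative), xenobiotic metabolism (5 of 7 positive) and hepatocyte transcription factors (8 of 11 negative) held no gene that passed. In lipid droplets and lipoproteins, Apoe, a lipoprotein component, passed adjusted over the list alone but not over all genes (limma adjusted p = 0.716), at 99.7, 127 and 240 FPKM in controls and 1.72, 118 and 0 after tunicamycin. Albumin was lower in 3 of 3 tunicamycin libraries without passing (log2 fold change -1.05, SE 0.79, limma adjusted p = 0.852).

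Of the 36 lists tested with camera, 0 passed, with 1 at an unadjusted p under 0.05 (acute phase response, p = 0.0345, adjusted p = 0.734), and 0 passed with an estimated correlation (adjusted p = 0.914 for the acute phase list). fry called 0 as well, with the smallest p in amino acid and urea metabolism (p = 0.00715, adjusted p = 0.257, 4 of 7 negative). Adjusted over the list alone, the metallothioneins Mt1 and Mt2 passed in the acute phase list, Rplp2, Rpl11, Rps20 and Rps9 among the ribosomal proteins, Cox6b1 in the respiratory chain, H2-D1 in antigen presentation, and mt-Nd1 and mt-Cytb among the mitochondrially encoded genes. Mt1 lay at 486, 110 and 195 FPKM in controls and 0, 188 and 92.3 after tunicamycin, and Mt2 at 68.6, 532 and 72.5 and then at 1.30, 119 and 1.38. Cell cycle genes were positive for 14 of 30 (median -0.15, or -0.10 to 0.71 with 1 library left out, mean 0.34, camera adjusted p = 0.823). In simulated libraries, with 1 molecule assumed for each multiple of the most frequent read number, limma recovered 1 of 67 genes changed 16-fold. The true number of molecules is not known, so this share need not apply to the libraries measured.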

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

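Usp14 was higher after tunicamycin in every setting run (log2 fold change 4.08 to 7.06, adjusted p 4.09e-20 to 0.799), as was Rpl15 (3.32 to 7.55). The 5 genes called by limma (4 higher, 1 lower) became 4 with a pseudocount of 0.1, 6 with 0.5, 6 rescaled as TPM, 4 with median-of-ratios scaling (4 higher, 0 lower), 4 with quantile normalization (4 higher, 0 lower), 6 at an adjusted p under 0.1 and 4 at a change of at least 1.5-fold. They became 2 (2 higher, 0 lower) with a mean FPKM of at least 0.1 and with at least 5, and 0 (0 higher, 0 lower) with no filter and without the variance trend. With the replicate block 0 genes were called (0 higher, 0 lower), and Usp14 and Rpl15 each had an adjusted p of 0.0726. Same-numbered libraries did not deviate together (correlations -0.0140 to 0.0023, against -0.0089 to 0.0179 for other numbers). With 85.5% of the genes tested at 0 in at least 1 library, this check could miss a pairing, so pairing is not excluded. Leaving out each library in turn gave 0 to 0 genes, 0 to 0 higher and 0 to 0 lower, with 184 to 299 genes at an unadjusted p under 0.05 by limma; the degrees of freedom of the limma variance prior were then 1.86 to 2.22, against an infinite prior with all 6. Chosen after seeing the data were edgeR on reads with 3 genes (3 higher, 0 lower), DESeq2 on reads with 44 (20 higher, 24 lower), genes above 0 in all 6 libraries with 2 (2 higher, 0 lower) and reads divided by the library peak with 2 (2 higher, 0 lower). mt-Cytb (-0.87 to 5.02 with a library left out) reversed without control 1, by edgeR (-0.23) and by DESeq2 (-0.11); control 1 alone held 0 reads of it. The cause of these changes was not tested. Gene lists called were 0 in every setting, fry, an estimated correlation and the replicate block included. Of the single gene and list values, 575 kept direction and side of the threshold, 65 lost the threshold, 2 gained it, 12 changed sign, or for a list the direction of its test, without a call in either setting, and 3 calls reversed. The median log2 fold change over the genes tested was 0.10, moved to 0.20 rescaled as TPM, and ranged from -0.17 to 0.32 over all settings. The 541022 to 661145 reads per library limit what can be detected, and if each bunch of genes stands for 1 molecule, which is not settled, single genes are limited more than these totals imply.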

Other observations

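All tests of explanations in this part were chosen after the results they address had been seen. Further gene lists went both ways or missed the threshold. Autophagy and lysosome genes had a negative log2 fold change for 16 of 22 members (median -0.37, or -1.11 to -0.11 with 1 library left out, camera adjusted p = 0.734), and Sqstm1, an autophagy receptor, lay at 267, 41.7 and 176 FPKM in controls and 70.4, 3.55 and 9.69 after tunicamycin. Glutathione and NRF2 target genes were positive for 10 of 20, p53 targets and apoptosis genes for 11 of 20, glycolysis, glycogen and insulin signalling genes for 7 of 14, and pericentral genes for 7 of 13. Phlda3 and Bax, both p53 targets, were at 0 in control 1 and control 2 and above 0 in the other 4 libraries (Bax at 43.7 FPKM in control 3 and 56.0, 50.2 and 44.9 after tunicamycin). Circadian genes were positive for 9 of 11 and cholangiocyte markers for 5 of 7, with camera adjusted p of 0.734 and 0.823.

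The proteasome, with which USP14 associates, was positive for 16 of 32 members (median 0.05, or -0.63 to 0.66 with 1 library left out, camera adjusted p = 0.890). Psmd14, a deubiquitinase of its lid, was at 0 in all 3 controls and at 19.0, 32.3 and 85.5 FPKM after tunicamycin (limma adjusted p = 0.852). Extracellular matrix genes were negative for 6 of 9, complement genes for 3 of 5, interferon response genes for 4 of 5, cytokine genes for 3 of 6, immediate early genes for 8 of 14, and substrates of IRE1-dependent decay for 3 of 5. Bile acid genes were positive for 4 of 6. No member of these lists passed over all genes or adjusted over the list alone.

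The first pattern is that most genes were at 0 while the reads of detected genes bunched at 1 number per library. Shallow sequencing alone would find the well-read genes of 1 library again in the others of its group, but of genes with at least 50 reads in 1 library, 22.6% to 51.0% held 0 reads in another, over 12 ordered pairs. Few starting molecules, each read many times, predict a second bunch at 2 molecules and cannot be told apart from other causes, because in only 2 of the 6 libraries did more genes lie near 2 times the bunch than near 1.5 times it beyond counting error (binomial p under 0.05). The counts near 2 times and near 1.5 times were 141 and 93, 298 and 292, and 318 and 259 in controls 1, 2 and 3, and 302 and 332, 242 and 206, and 252 and 218 in tunicamycin 1, 2 and 3. No biological explanation was tested for this pattern, which was present in both groups, and differences between animals stay open.

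The second pattern is that many liver genes, plasma protein and periportal genes among them, were listed at 0 in all 6 libraries. Too few reads would spare the most abundant liver mRNAs, but the share at 0 was 85.3 percentage points higher for plasma protein genes than for cell cycle genes. Merged loci in the authors' counting also leave the pattern standing, since 80.0% of plasma protein genes with an unmerged locus (20 of 25) were at 0. A filter in the authors' processing that removed these genes was not tested, and for the genes at 0 another cell source cannot be told apart from it. Alb was not removed, yet its mean of 248 FPKM in controls and 119 after tunicamycin lay below that of Actb (1518 and 1622). A filter that removes genes would not lower a gene it kept, so such a filter alone does not account for the level of Alb. The best detected of 12 marker lists of other cell types, that of cholangiocytes, was above 0 for 46.7% of its genes, where 8738 of all 22564 genes were above 0 in at least 1 library. The 4 Y-linked genes bear on sex and not on tissue. Their reads, 0.0495% of those of their X-linked partners, go against the label male unless these genes were filtered too. Whether the labels describe these libraries is therefore not settled. No biological explanation was tested for this pattern, which includes the controls by definition.

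The third pattern is the rise of Usp14. If the bunch of a library stands for 1 molecule, which is not settled, a few amplified molecules would give reads close to it. Usp14 held at least 30.1 times that number in each tunicamycin library, against 1.95, 1.67 and 0.0749 times in controls 1, 2 and 3. Without that assumption, uneven amplification of a few molecules stays open. Induction together with the unfolded protein response cannot be told apart from a change in Usp14 alone. The rule counted only a fall of the ER chaperone list against it, and the list missed the threshold (camera adjusted p = 0.734, 14 members positive and 10 negative). The test therefore could not decide. No rise on the scale of Usp14 was seen in that list. Its median log2 fold change was 0.31, or 0 to 0.46 with 1 library left out, against 6.64 for Usp14. Camera recovered 4 of 5 lists shifted 2-fold in simulated libraries, whose numbers of molecules were assumed. A construct with little 3' UTR cannot be told apart from an endogenous transcript. The length implied by reads and FPKM had a median of 2411 nt over the tunicamycin libraries. It was 1.17 to 1.21 times the shortest annotated coding transcript of 2019 nt, above the 90th percentile of that ratio over genes with 1 annotated transcript (1.04 to 1.06). It was 0.50 to 0.52 times the longest of 4726 nt. It matched neither, and the implied length in control 3 was 2046 nt. FPKM was scaled to annotated transcripts, and a mix of them could give a value between these lengths. The implied length therefore does not measure the molecule sequenced, and this test could not decide.

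The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 5 genes and the highest of the others called 7, and 3 of the 10 splits, the real one included, called at least 5. For gene lists the real split called 0 and the highest other 2, and since 10 of 10 splits must call at least 0, that count decides nothing.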
